A study of Homo sapiens with 6 samples.

How the data were processed

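The deposited values were whole-number read counts per gene and library. Per the submitters' processing notes, reads were converted with bcl2fastq, aligned with STAR 2.5 to the hg38 build, counted with featureCounts from Subread 1.6.5, and analysed with edgeR 3.20.8. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit. No source used here states the strand setting of the counting, the annotation release, the edgeR test or the sequence of the hairpin. The deposited count table held 63299 genes, each with an identifier and a name, and 0 entries without a gene name. Of the identifiers, 57447 occur in GENCODE 29 on GRCh38, and 55290 have the same coordinates there. Gene types and annotated 3' UTRs were taken from that release. Genes on unplaced or alternative scaffolds (5262) held at most 0.0064% of a library's counts.

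The main test was computed here from the deposited counts with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, genes with too few reads were removed with filterByExpr using the group, and knockdown was compared with control in a quasi-likelihood F test, two-sided. P-values were adjusted by Benjamini-Hochberg over all tested genes, and an adjusted p under 0.05 was called a change. Log2 fold changes are knockdown minus control, with the standard error of the fitted coefficient. CPM values are counts scaled to a common library total in the usual way, given as mean and SD over 3 libraries. Alternatives used DESeq2 1.42.0 and limma 3.58.1. Sets of genes were tested with camera, with a preset inter-gene correlation of 0.01 and adjustment over the 30 lists, and again with an estimated correlation and with fry. With an estimated correlation camera has only the residual degrees of freedom, given below, so a call lost there is weak evidence of no change.

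The design, the main test, the alternatives for each processing choice, the 30 gene lists and the rule for named genes were set before the data were examined. The named genes were the members of the PRMT5 methylosome list, and the 8 higher and 8 lower coding genes with the largest fold change among those past the threshold. These 16 needed group ranges without overlap and a mean of at least 1 CPM in a group. The rule added the 3 members of each other list with the smallest adjusted p, whether or not they passed. It also named genes fixed by symbol, among them KLK3, TMPRSS2, BRCA1, CDKN1A, MDM2, MDM4, CCND1, MYC and E2F1, and a few of the genes the rule named are not reported here.

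The library titles number the replicates 1 to 3 in both groups, and the series design text calls them biological replicates. Whether a number marks a shared culture was checked from the data, by correlating each library's deviations from its group mean over the tested genes. Libraries with the same number had correlations of 0.554, 0.381 and 0.358, and libraries with different numbers had correlations from -0.39 to 0.06. The numbers therefore appear to pair the libraries. The main test was set before this check and ignores the pairing, as do the fits that left out 1 library. A fit with the replicate number as a block is given wherever it changed a call or moved a count by more than 1.5 times. All 84 named genes called without the block were also called with it. The biological coefficient of variation was 20.8% without the block and 11.9% with it. The residual degrees of freedom were 4 and 2.

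Both fits were first run on simulated counts drawn from the real means, dispersions and library sizes, with a known set of changed genes. The counts for the fit without the block held no pair effect. Those for the block fit held a pair effect of a chosen size and the dispersions of that fit. Far fewer genes were changed than were called in the real data. The shares therefore need not hold for the real data and do not compare the 2 fits on the same counts. Without the block, for knockdown against control over 20648 simulated genes, 4.5% of the genes changed by a log2 of 0.5 were called. The share was 47% at a log2 of 1 and 87.5% at a log2 of 2, and 9.1% of the calls were unchanged genes. With the block, over 20611 genes, those shares were 32.8%, 69.6% and 97%, and 4.5% of the calls were unchanged genes. Camera called 0 of the simulated lists of 40 unchanged genes in either fit. The simulated genes were drawn independently, so this does not show how camera acts on lists with correlated members. A search for 7-base words in 3' UTRs ranked a planted word first of all words in both simulations with one, over 13228 genes.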

Results

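The series measured messenger RNA in LNCaP cells, a human prostate cancer line that depends on androgen, by RNA sequencing. The cells carried a short hairpin RNA, induced by doxycycline, against MEP50, the cofactor of the arginine methyltransferase PRMT5. The gene of MEP50 is WDR77. There were 3 libraries from cells given doxycycline, called knockdown here, and 3 from cells without it, called control. The knockdown libraries held 18568002, 36001219 and 20682236 counts on genes for replicates 1, 2 and 3, and the control libraries held 27509105, 29943841 and 36234784. The question of the comparison was which genes change in LNCaP cells when MEP50 is lowered. No library received doxycycline without the hairpin, so drug and knockdown cannot be separated in these data.

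The WDR77 transcript was lower in every knockdown library than in every control library. The 3 knockdown libraries held 15.05, 14.03 and 12.73 CPM, from 281, 519 and 278 reads, and the 3 control libraries held 49.28, 47.16 and 36.71 CPM, from 1270, 1416 and 1286 reads. WDR77 (ENSG00000116455.13, chromosome 1, 111439890 to 111449376, hg38) thus fell 3.18-fold, from 44.4 ± 6.73 to 13.9 ± 1.16 CPM (SD, n = 3 libraries per group). Its log2 fold change was -1.67 (SE 0.16, adjusted p 0.00131, edgeR quasi-likelihood test). It was called in each fit that left out 1 library, with log2 fold changes from -1.80 to -1.55. Its coding sequence holds the 7-base word ACTCTGT once, in exon 5 of 10, and its annotated 3' UTR lacks the 6-base word CTCTGT.

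PRMT5, the enzyme that MEP50 binds, fell less, by a log2 of 0.53 (145 ± 3.73 against 210 ± 16 CPM, adjusted p 0.0268, edgeR). The antioxidant enzyme PRDX1, which was in the same list, fell by 0.57 (adjusted p 0.0443). Either call ended when any library other than control replicate 2 was left out, with adjusted p up to 0.119 for PRMT5 and 0.177 for PRDX1, PRDX1 also lost it with RLE scaling, and both were called with the replicate pairs as a block (0.00165 and 0.00427). PRMT5 overlaps PRMT5-AS1 on the other strand, so part of its reads could belong to that gene. The other genes in the PRMT5 methylosome list, CLNS1A, RIOK1, COPRS and TXN, had log2 fold changes of 0.02, -0.21, -0.04 and -0.17 and were not called. The list of 7 includes WDR77, the target of the hairpin, so its call does not test the other members alone. Its median was -0.21 and camera called it lower (adjusted p 0.00295). That call was lost with an estimated correlation (0.403) and in fry (0.0904). The 3 lower members of the list, WDR77 included, were also 3 when adjusted over the list alone. They were 1, WDR77, after leaving out any library other than control replicate 2. Among 10 other arginine methyltransferases and demethylases, edgeR called 0, with 2 at an unadjusted p under 0.05, and DESeq2, limma-voom and edgeR's exact test also called 0. With the pairs as a block 4 were called, 2 higher and 2 lower, and adjusted over the list alone 0 were called without the block. The 3 with the smallest p in that list were PRMT6 (-0.39, block adjusted p 0.0112), JMJD6 (-0.46, 0.0155) and PRMT3 (-0.29, 0.0733). The list as a whole was not called (median -0.19, camera adjusted p 0.328).

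**Figure D1:**
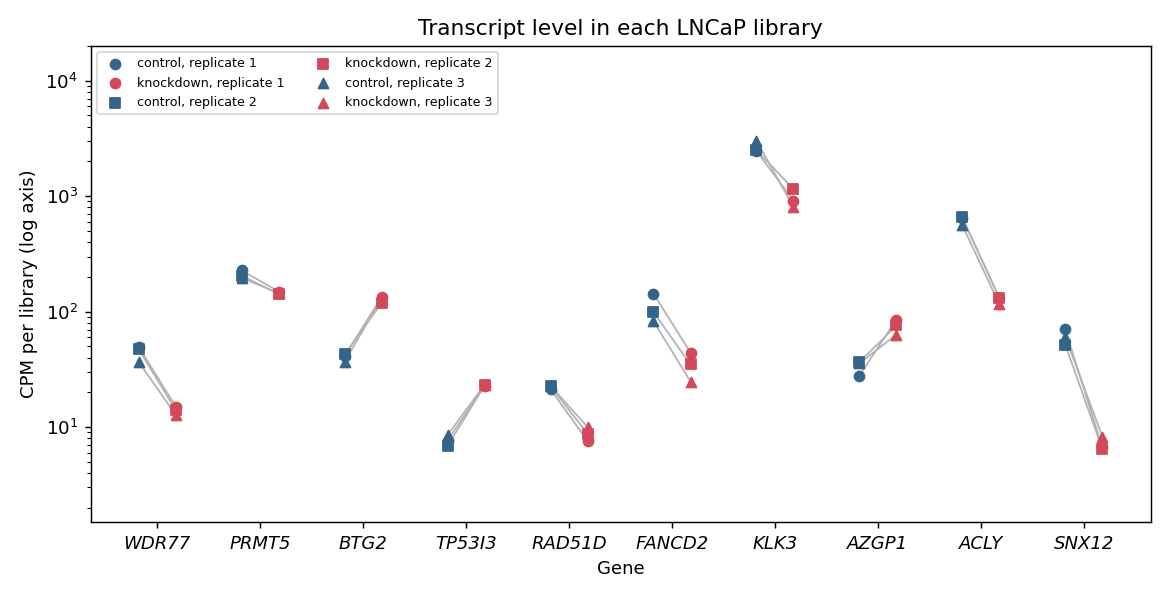
CPM (counts scaled to a common library total) of 10 genes in each of the 6 LNCaP libraries, on a log axis, with blue for control and red for knockdown. Marker shapes give the replicate and lines join libraries with the same replicate number, and for each gene shown the 3 knockdown libraries lie on the same side of the 3 control libraries (WDR77 12.73 to 15.05 against 36.71 to 49.28 CPM).

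Over the transcriptome, more genes fell than rose, and the falls were concentrated among abundant coding transcripts. Of 21101 tested genes, 574 were higher and 1029 lower in knockdown (1603 in all, 7.6%, edgeR, adjusted p under 0.05). With the pairs as a block the counts were 2358 higher and 3148 lower, and all 1603 calls were among these with the same direction. At least a 2-fold change was shown by 349 of the higher and 451 of the lower genes, and with the block by 727 higher and 676 lower, where more rose than fell. Group ranges without overlap were found for 6406 genes, 30.4% of those tested. Chance gives 10% for libraries that can be exchanged freely, a figure that does not allow for the pairing by replicate number. Above 64 CPM 90 genes were higher and 393 lower (402 and 1115 with the block), and below 1 CPM 88 were higher and 24 lower (295 and 88). Of 13463 coding genes 402 were higher and 904 lower (1615 and 2677 with the block), and of 1446 processed pseudogenes 29 were higher and 6 lower (132 and 39). The 1603 calls became 497 without knockdown replicate 2, 681 without knockdown replicate 3, 818 without control replicate 1 and 889 without control replicate 3. Higher calls also became 348 without knockdown replicate 1.

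**Figure D2:**
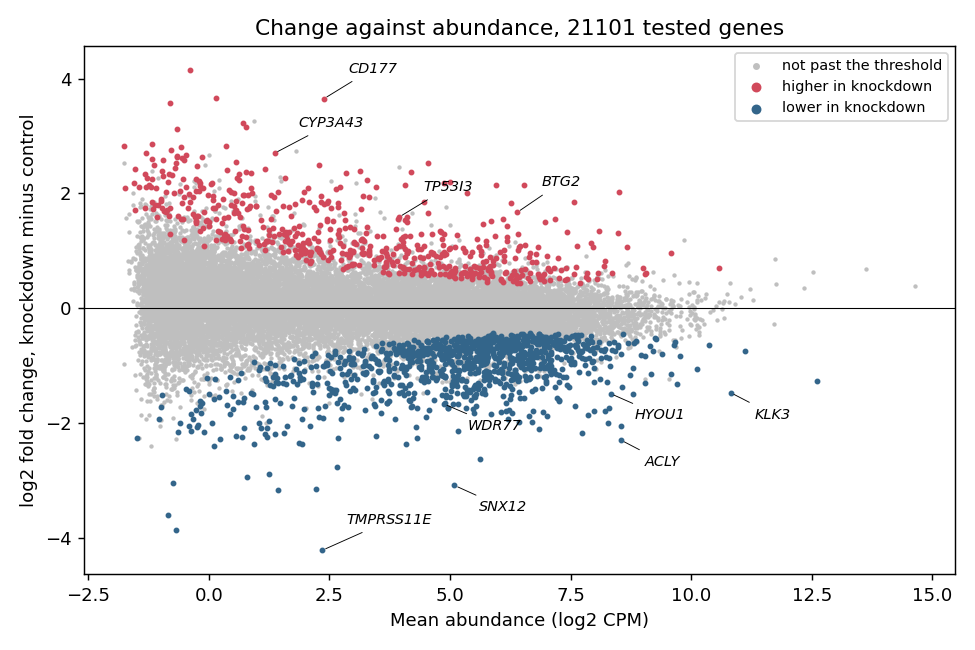
Log2 fold change, knockdown minus control, against mean abundance in log2 CPM for the 21101 tested genes, 1 point per gene. Red points are the 574 higher genes and blue points the 1029 lower genes past an adjusted p of 0.05, and most blue points lie at higher abundance than most red points.

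The largest falls among coding genes joined transcripts of several kinds. TMPRSS11E, a membrane serine protease (ENSG00000087128.9), fell from 9.48 ± 0.89 to 0.49 ± 0.15 CPM (log2 fold change -4.22, SE 0.27, adjusted p 0.000219, edgeR). SNX12, a sorting nexin (ENSG00000147164.11, X chromosome), fell from 60.9 ± 9.14 to 7.15 ± 0.99 CPM (-3.09, SE 0.18, adjusted p 0.000219). The secreted chaperone CLU fell by a log2 of 2.76, from 10.8 ± 1.80 to 1.57 ± 0.43 CPM. The remaining large falls were CRISP3 (-3.87), the keratin KRT19 (-3.17), the olfactory receptor OR51E1 (-3.15), DOCK8 (-2.95) and the oxidase NOX5 (-2.90). CRISP3 lost its call without knockdown replicate 2 (adjusted p 0.0614). OR51E1 lost it without knockdown replicate 2 or 3 or control replicate 2 or 3 (up to 0.148), and in DESeq2, limma-voom and thinned counts, and its log2 fold change was -2.51 without control replicate 3. TMPRSS11E, SNX12, CRISP3, OR51E1, DOCK8 and NOX5 have the 6-base word CTCTGT in their annotated 3' UTR, and CLU and KRT19 lack it.

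The largest rises were mostly in genes with few reads in control cells. CYP3A43, a cytochrome P450 (ENSG00000021461.16), rose from 0.68 ± 0.09 to 4.41 ± 1.45 CPM (log2 fold change 2.70, SE 0.33, adjusted p 0.00293, edgeR), and the receptor FGFR2 rose from 0.42 ± 0.12 to 2.5 ± 0.46 CPM (2.55, SE 0.32, adjusted p 0.0035). CD177 rose by 3.65, the transporter ABCB5 by 3.22 and MUC19 by 2.62, and these were called whichever library was left out. PRAMEF12 rose by 4.15, the chemokine CXCL10 by 3.66 and NLGN1 by 2.53. Several rises were smaller without knockdown replicate 1, with log2 fold changes of 2.72 for CD177, 2.88 for PRAMEF12, 2.69 for CXCL10 and 1.72 for NLGN1. Without control replicate 1 they were 4.68 for CXCL10 and 3.51 for NLGN1. PRAMEF12 lost its call without any control replicate (adjusted p up to 0.0779). CXCL10 lost it without knockdown replicate 1 or 2 or control replicate 2 or 3 (up to 0.102), and in limma-voom. NLGN1 lost it without any library other than control replicate 1 (up to 0.138). PRAMEF12 belongs to a family of near-identical copies, so its reads may be shared with others.

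Lists of DNA replication, mitosis and histone genes were lower, with the lowest list medians in the comparison. The 45 tested G1/S and DNA replication genes had a median log2 fold change of -0.90 and the 41 G2/M and mitosis genes one of -1.02 (camera adjusted p 6.39e-19 and 2.44e-17, with estimated correlation 0.403 for both). The 37 tested replication-dependent histone genes had a median of -1.16 (camera adjusted p 1.13e-17, with estimated correlation 0.326). In every replicate pair the median of each of these lists was below -0.90. The groups nearly met when each library was set against the mean over all libraries. G2/M medians were then 0.95, 0.52 and 0.07 in control replicates 1 to 3 and 0.05, -0.47 and -1.14 in knockdown replicates 1 to 3. Control replicate 3 and knockdown replicate 1 had -0.01 and -0.08 for G1/S, and 0.13 and -0.18 for histone genes. RFC3, a clamp loader subunit, fell from 57.0 ± 11.7 to 20.1 ± 2.64 CPM (-1.50, SE 0.19, adjusted p 0.00324, edgeR). RRM2 fell by 2.10, CHAF1A by 1.12, ANLN by 1.88, the proliferation marker MKI67 by 1.57, H1-5 by 1.71, H4C1 by 1.39 and H2BC13 by 1.38. These 7 lost their calls without knockdown replicate 2, with adjusted p of 0.0545, 0.0526, 0.0629, 0.0533, 0.0545, 0.0601 and 0.0573. PLK1 fell by 1.27 and E2F1 by 1.51. PLK1 lost its call without knockdown replicate 2 or 3 or control replicate 1 or 2 (up to 0.118), and E2F1 without knockdown replicate 2 or control replicate 1 or 2 (up to 0.0826).

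Calls of single cell cycle genes depended on the fit more than the list medians did. Without the block 15 G1/S, 8 G2/M and 19 histone genes were lower, and with it 43, 40 and 31 were. Adjusted over the list alone the counts were 39, 37 and 29 without the block. The 15 G1/S genes became 1 without knockdown replicate 2, 7 without knockdown replicate 3, 6 without control replicate 1 and 8 without control replicate 2. The 8 G2/M genes became 27 without knockdown replicate 1, 0 without knockdown replicate 2, and 2 without knockdown replicate 3, control replicate 1 or control replicate 2. The 19 histone genes became 1 without knockdown replicate 2, 7 without knockdown replicate 3 and 12 without control replicate 1. Of all called lists, the p53 target and fatty acid lists alone held their call in camera with an inter-gene correlation estimated from the data (0.0181 and 0.0467), and with the block these had 0.141 and 0.211. RFC3, RRM2, MKI67 and E2F1 have the word CTCTGT in the 3' UTR, CHAF1A, ANLN, PLK1 and H2BC13 lack it, and H1-5 and H4C1 have no annotated 3' UTR. Histone genes are near-identical in sequence, so reads could be split among copies.

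Some DNA repair genes also fell. The 36 homologous recombination and Fanconi genes had a median of -0.53 (camera adjusted p 1.66e-06, with estimated correlation 0.403), and the 28 end joining and damage checkpoint genes one of -0.45 (0.000289, with estimated correlation 0.403). Set against the mean over all libraries, the recombination median was 0.011 in knockdown replicate 1, above the -0.004 of control replicate 3. The end joining median was -0.04 and -0.01 in these libraries. FANCD2, a Fanconi anemia protein gene (ENSG00000144554.10, chromosome 3, 10026414 to 10101930), fell from 109 ± 31.4 to 34.6 ± 9.65 CPM (-1.65, SE 0.25, adjusted p 0.00725, edgeR). RAD51D fell from 22.2 ± 0.80 to 8.80 ± 1.21 CPM (-1.34, SE 0.16, adjusted p 0.00302). Both were called whichever library was left out, and both have the word CTCTGT in the 3' UTR, as do 50.8% of all genes searched. MDC1, RNF168 and LIG3 also have it, and BRCA1 lacks it. Recombination genes had a median of -0.52 with the word and -0.57 without it, and end joining genes -0.63 and -0.37. BRCA1 fell by 0.96 (adjusted p 0.045), a call lost without knockdown replicate 2 or 3 or control replicate 1 or 2 (up to 0.132). MDC1 fell by 1.42, RNF168 by 0.79 and LIG3 by 0.55. MDC1 lost its call without knockdown replicate 2 or 3 (up to 0.0696), RNF168 also without control replicate 1 (up to 0.0848), and LIG3 without any library other than control replicate 2 (up to 0.0982). The recombination list had 9 lower and 1 higher calls, 15 and 2 adjusted over the list alone, and 22 and 2 with the pairs as a block. Its 9 became 3 without knockdown replicate 2, 4 without knockdown replicate 3 and 3 without control replicate 1, and its 1 higher call was lost without any library. The end joining list had 5 lower calls, 8 adjusted over the list alone and 15 with the block. Those 5 became 0 without knockdown replicate 2 or 3, 1 without control replicate 1, and 3 without any of the other libraries.

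Many targets of p53 rose, against the fall of cell cycle and repair genes. Of 34 tested targets 12 were higher and 0 lower in edgeR, and adjusted over the list alone 23 were higher and 2 lower. With the pairs as a block 26 were higher and 2 lower. The median was 0.58 (camera adjusted p 1.38e-16, with estimated correlation 0.0181, and 0.141 when the block is added to that), with medians of 0.62, 0.68 and 0.62 in the 3 pairs. The antiproliferative gene BTG2 (ENSG00000159388.5, chromosome 1, 203305491 to 203309602) rose from 40.3 ± 3.02 to 128 ± 8.07 CPM (1.67, SE 0.12, adjusted p 0.000614, edgeR). TP53I3 rose from 7.68 ± 0.84 to 23.1 ± 0.23 CPM (1.58, SE 0.16, adjusted p 0.00131), and SPATA18 rose by 1.26. These were called whichever library was left out, and BTG2 and SPATA18 rose although their 3' UTRs have the word CTCTGT. CDKN1A, which encodes the inhibitor p21, rose by 0.48 and was not called (adjusted p 0.13), but was with the block (0.0092). MDM2 also rose by 0.48 (0.057, and 0.00558 with the block), and MDM4 was 0.21 higher without a call in either fit.

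Among D cyclins, CDKs and CDK inhibitors the median was -0.41 over 19 genes (camera adjusted p 0.00212, with estimated correlation 0.395). CCND1, the gene of cyclin D1, fell from 299 ± 48.8 to 149 ± 26.4 CPM (-1.0, SE 0.17, adjusted p 0.0118, edgeR), CDKN1B fell by 0.87 and CDKN2D by 0.98. CCND1 and CDKN1B have the word CTCTGT in the 3' UTR, and CDKN2D lacks it. CDKN2D lost its call without knockdown replicate 2 or 3 (up to 0.0661). The list had 6 lower calls, 9 lower and 1 higher adjusted over the list alone, and 10 lower and 1 higher with the block. The 6 became 2 without knockdown replicate 2, and 3 without knockdown replicate 3 or control replicate 1. MYC was 0.53 lower, which was not called (0.0751) without the block and was with it (0.0027).

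Genes that androgen induces fell in part. KLK3, the gene of prostate-specific antigen (ENSG00000142515.14, chromosome 19, 50854915 to 50860764), fell from 2664 ± 318 to 957 ± 178 CPM (-1.48, SE 0.18, adjusted p 0.0027, edgeR). TMEM140 fell by 0.96, and AZGP1 rose by 1.17, from 33.3 ± 4.74 to 74.8 ± 11 CPM, and these 3 were called whichever library was left out. TMPRSS2 fell by 1.14 (adjusted p 0.0437), a call lost without any library other than control replicate 1 (up to 0.117). KLK3, TMPRSS2 and AZGP1 have the word CTCTGT in the 3' UTR, and TMEM140 lacks it. KLK3 shares much sequence with its neighbour KLK2. The 49 androgen-induced genes had a median of -0.28 (camera adjusted p 0.000666, with estimated correlation 0.403). They had 10 lower and 1 higher calls, 15 and 4 adjusted over the list alone, and 22 and 6 with the pairs as a block. The 10 became 5 without knockdown replicate 2, 4 without knockdown replicate 3 and 5 without control replicate 3, where 2 were higher.

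Androgen-repressed genes and cofactors moved in both directions. The 14 androgen-repressed genes had a median of 0.37 and were not called by camera (adjusted p 0.318), but were with the block (0.0151), a call lost with the block and an estimated correlation (0.334). SESN1, which is also a p53 target, rose by 0.91, ACKR3 rose by 1.55 and CAMK2N1 fell by 1.41. ACKR3 lost its call without knockdown replicate 3 or control replicate 1 or 2 (up to 0.0811), and CAMK2N1 without knockdown replicate 1 or 2 or control replicate 2 or 3 (up to 0.132). That list had 2 higher and 1 lower calls, 2 and 2 adjusted over the list alone, and 7 and 3 with the block. Its 2 higher calls became 1 without knockdown replicate 3 or control replicate 1 or 2. The 20 cofactors and lineage factors were not called as a list (median -0.12, camera adjusted p 0.453). Of these ETV1 fell by 1.28, a call lost without knockdown replicate 2 or control replicate 3 (up to 0.067). FOXP1 was 0.42 higher and NCOA3 0.41 lower, without a call, but with one in the block fit (0.0086 and 0.0122). The list had 1 lower call, 1 adjusted over the list alone, and 4 higher and 4 lower with the block.

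A few splicing genes fell. The 32 Sm ring, SMN complex and snRNP genes had a median of -0.27 and the 34 SR proteins and splicing regulators one of -0.28 (camera adjusted p 0.00109 and 0.00133, with estimated correlation 0.503 and 0.403). The core protein gene SNRPD2 fell from 111 ± 24.0 to 31.8 ± 3.71 CPM (-1.80, SE 0.18, adjusted p 0.00149, edgeR), and the splicing repressor PTBP1 fell from 183 ± 39.3 to 85.9 ± 13.5 CPM (-1.09, SE 0.18, adjusted p 0.0101). Both have the word CTCTGT in the 3' UTR. SNRPA fell by 0.75, a call lost without knockdown replicate 2 (0.0721), and U2AF2 by 0.69, a call lost without knockdown replicate 2 or 3 or control replicate 1 (up to 0.0746). U2AF2 has the word, and SNRPA lacks it. SNRPA1 (-0.58) and HNRNPH1 (-0.63) were not called, but were with the block (0.0058 and 0.00148). The first list had 2 lower calls, 4 adjusted over the list alone, and 10 lower and 1 higher with the block, and its 2 became 1 without knockdown replicate 2. The other had 2, 2 adjusted over the list alone and 15 with the block, and its 2 became 1 without knockdown replicate 2 or 3 or control replicate 1. SMN1 and SMN2 in that first list are near-identical, so their reads could not be told apart.

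Some lipid synthesis genes fell, ACLY the most of those named. ACLY, which makes cytosolic acetyl-CoA (ENSG00000131473.16, chromosome 17, 41866908 to 41930542), fell from 622 ± 52.4 to 126 ± 9.09 CPM (-2.30, SE 0.13, adjusted p 0.000219, edgeR). FADS1 fell by 1.29 and ACSS2 by 1.10, and DHCR7 and FDPS of sterol synthesis fell by 0.79 and 0.91. These genes were called whichever library was left out. The 16 fatty acid genes had a median of -0.39 (camera adjusted p 1.73e-08, with estimated correlation 0.0467, and 0.211 when the block is added to that), with 5 lower calls, 6 adjusted over the list alone and 7 with the block. In that list 11 genes have the word CTCTGT in the 3' UTR, with a median of -0.56, and the 5 without it had a median of 0.03. The 23 sterol genes had a median of -0.49 (camera adjusted p 6.00e-07, with estimated correlation 0.239), and the 12 of these without the word had one of -0.46. They had 6 lower calls, 12 adjusted over the list alone and 14 with the block, and the 6 became 2 without knockdown replicate 2 and 11 without control replicate 2.

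Nuclear genes of mitochondrial respiration and translation were lower as lists, by small amounts. Nuclear respiratory chain genes (47) had a median of -0.20 and mitochondrial ribosome and translation genes (40) one of -0.23 (camera adjusted p 7.52e-05 and 0.00186, with estimated correlation 0.491 and 0.503). ATP5F1B, a subunit of ATP synthase, fell from 1505 ± 109 to 721 ± 31.0 CPM (-1.06, SE 0.13, adjusted p 0.00291, edgeR), UQCRFS1 by 0.98 and NDUFB10 by 0.89. MRPL15 fell by 0.73, TSFM by 0.55 and MRPS11 by 0.54. MRPL15 lost its call without knockdown replicate 2 or 3 or control replicate 1 (up to 0.062), TSFM without any library other than control replicate 2 (up to 0.156), and MRPS11 without any library (up to 0.159) and with RLE scaling. The respiratory list had 7 lower calls, 7 adjusted over the list alone and 16 with the block, and the 7 became 3 without knockdown replicate 2 or 3 and 4 without control replicate 1 or 3. The translation list had 4, 4 adjusted over the list alone and 10 with the block, and the 4 became 0 without knockdown replicate 2 or 3 or control replicate 1, 1 without knockdown replicate 1 or control replicate 3 and 2 without control replicate 2. ATP5F1B, NDUFB10, TSFM and MRPS11 have the word CTCTGT in the 3' UTR, and UQCRFS1 and MRPL15 lack it. Respiratory genes with the word had a median of -0.18 and those without it -0.23, and translation genes had -0.24 in both cases.

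The 13 mitochondrially encoded mRNAs were not called as a list (median 0.23, camera adjusted p 0.274). EdgeR called 0 of them, with 0 at an unadjusted p under 0.05, and DESeq2, limma-voom and the exact test called 0, and adjusted over the list alone 0 were called. MT-CYB was 0.41 higher, and was the 1 member called with the block (0.00959), with MT-CO3 0.33 lower and MT-ND5 0.38 higher. Of 73 cytosolic ribosomal protein genes edgeR called 0, with 5 at an unadjusted p under 0.05, DESeq2 and the exact test 1 each, limma-voom 0 and the block fit 4, and adjusted over the list alone 0 were called. RPS25 was 0.69 lower and RPL13A 0.42 higher, with calls in the block fit (0.00656 and 0.0325), RPL8 was 0.32 lower, and the list was not called (median 0.04, camera adjusted p 0.328), but was without control replicate 3 (0.0212). Ribosomal protein genes have many processed copies, so their reads could be split. Glycolysis and hypoxia genes (32) had a median of -0.37 (camera adjusted p 7.52e-05, with estimated correlation 0.0932). GPI fell by 1.05, LDHA by 0.81 and NDRG1 by 1.10, where LDHA lost its call without knockdown replicate 2 or 3 or control replicate 1 (up to 0.0614), and NDRG1 without knockdown replicate 2 or 3 or control replicate 3 (up to 0.0934). That list had 9 lower calls, 13 lower and 2 higher adjusted over the list alone, and 16 lower and 2 higher with the block. The 9 became 1 without knockdown replicate 2, 2 without knockdown replicate 3 or control replicate 1 and 3 without control replicate 3.

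Some genes of the endoplasmic reticulum stress response fell. The 24 genes had a median of -0.39 (camera adjusted p 1.50e-07, with estimated correlation 0.326), with 5 lower calls, 11 adjusted over the list alone, and 12 lower and 1 higher with the block, and the 5 became 8 without control replicate 2. The chaperone HYOU1 fell from 475 ± 53.5 to 169 ± 18 CPM (-1.49, SE 0.14, adjusted p 0.00111, edgeR), EDEM1 by 1.08 and MANF by 0.97, and all 3 have the word CTCTGT in the 3' UTR. The 39 ATF4 targets of the integrated stress response had a median of -0.31 and were not called (camera adjusted p 0.112), but were with the block (0.00113), without knockdown replicate 3 (4.98e-05) and without control replicate 1 (0.000189). With the block and an estimated correlation the adjusted p was 0.438. PSAT1 of that list fell by 1.86, a call lost without knockdown replicate 2 (0.0649), and PPP1R15A was 0.81 higher and PYCR1 0.52 lower, without a call, but with one in the block fit (0.00494 and 0.00191). The list had 1 lower call, 1 adjusted over the list alone, and 17 lower and 3 higher with the block.

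A few interferon-stimulated and immediate early genes changed, and both lists were called higher by camera but not with an estimated correlation or by fry (0.294 and 0.13). The 31 interferon-stimulated genes had a median of 0.16 (camera adjusted p 0.0376, with estimated correlation 0.553), which was lost without knockdown replicate 1 (0.336), control replicate 2 (0.215) or control replicate 3 (0.079). IRF1 rose by 1.53, TRIM22 rose by 1.78 and OAS3 fell by 1.33. IRF1 and TRIM22 lost their calls without knockdown replicate 2 (0.0525 and 0.0744), and OAS3 without knockdown replicate 2 or control replicate 1 (up to 0.0687). The list had 4 higher and 2 lower calls, 5 and 2 adjusted over the list alone, and 14 and 2 with the block. Its 4 higher calls became 2 without knockdown replicate 1, control replicate 2 or control replicate 3 and 0 without knockdown replicate 2. Its 2 lower calls became 0 without knockdown replicate 2 or control replicate 1 and 1 without knockdown replicate 3 or control replicate 3. The 16 immediate early genes had a median of 0.42 (camera adjusted p 0.0298, with estimated correlation 0.403), which was lost without control replicate 1 (0.12). JUN rose by 1.27, a call lost without knockdown replicate 2 or control replicate 1 or 3 (up to 0.0863), which left 0 of the 1 higher call. EGR1 (2.25) and FOS (1.10) were not called, but were with the block (0.00912 and 0.016). The list had 3 higher and 1 lower calls adjusted over the list alone, and 8 and 3 with the block.

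A few luminal markers fell, and 1 stromal marker, VIM, rose. The 16 luminal markers had a median of -0.26 (camera adjusted p 0.00687, with estimated correlation 0.239), with 4 lower calls, 4 adjusted over the list alone, and 6 lower and 2 higher with the block. KRT18 fell by 0.59 and MSMB by 1.59, besides KRT19. KRT18 lost its call without any library other than control replicate 2 (up to 0.0723), and MSMB without any knockdown replicate or control replicate 1 (up to 0.082). The 4 luminal calls became 1 without any knockdown replicate, and 2 without control replicate 1 or 3. The 15 stromal markers had a median of 0.35 (camera adjusted p 0.0281, with estimated correlation 0.403), which was lost without knockdown replicate 1 (0.109) or control replicate 3 (0.131). VIM rose from 2.38 ± 1.14 to 12.2 ± 8.82 CPM (2.35, SE 0.51, adjusted p 0.0277, edgeR), a call lost without control replicate 2 or 3 (up to 0.0947), and its log2 fold change was 1.57 without knockdown replicate 1. ACTA2 was 0.67 higher and S100A4 1.13 higher, without a call, but with one in the block fit (0.0204 and 0.032). That list had 1 higher call, 1 adjusted over the list alone and 4 with the block, and the 1 became 2 without control replicate 1 and 0 without control replicate 2 or 3.

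The lists of 3 other cell types were not called. Of 13 basal markers 5 could be tested (median -0.32, camera adjusted p 0.142), and without knockdown replicate 3 that list was called (0.0322). KRT14 fell by 3.60 from 0.85 ± 0.23 CPM, with 20, 20 and 39 reads in control and 0, 0 and 5 in knockdown libraries, so the size of its fall is uncertain. It had a log2 fold change of -2.77 without knockdown replicate 2, and without knockdown replicate 3 no knockdown reads were left to give a size. DST fell by 0.54 and ITGB4 was 0.98 higher without a call. KRT14 lost its call without knockdown replicate 1 or 2 or control replicate 1 or 3 (up to 0.118), and DST without any library other than control replicate 2 (up to 0.154), with RLE scaling and in thinned counts. The 2 lower basal calls, 2 adjusted over the list alone, became 1 without knockdown replicate 3 and 0 without knockdown replicate 1 or 2 or control replicate 1 or 3. Of 18 neuroendocrine markers 7 could be tested (median 0.10, camera adjusted p 0.996). POU3F2 rose by 1.74 to 0.53 ± 0.12 CPM, a call lost without any library (up to 0.157) and in DESeq2. SYP was 0.76 lower and ENO2 0.60 lower, without a call, but with one in the block fit (0.0224 and 0.0051). That list had 1 higher call, 1 higher and 1 lower adjusted over the list alone, and 1 higher and 2 lower with the block. Of 16 leukocyte and endothelial markers 4 could be tested, with a median of -0.44 but a mean of 0.27, and camera's direction was up (adjusted p 0.661). LYZ rose by 2.75 to 0.90 ± 0.24 CPM, VWF was 0.73 lower without a call, but with one in the block fit (0.000632), and CD68 was 0.81 lower without a call. That list had 1 higher call, 1 adjusted over the list alone, and 1 higher and 1 lower with the block.

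**Figure D3:**
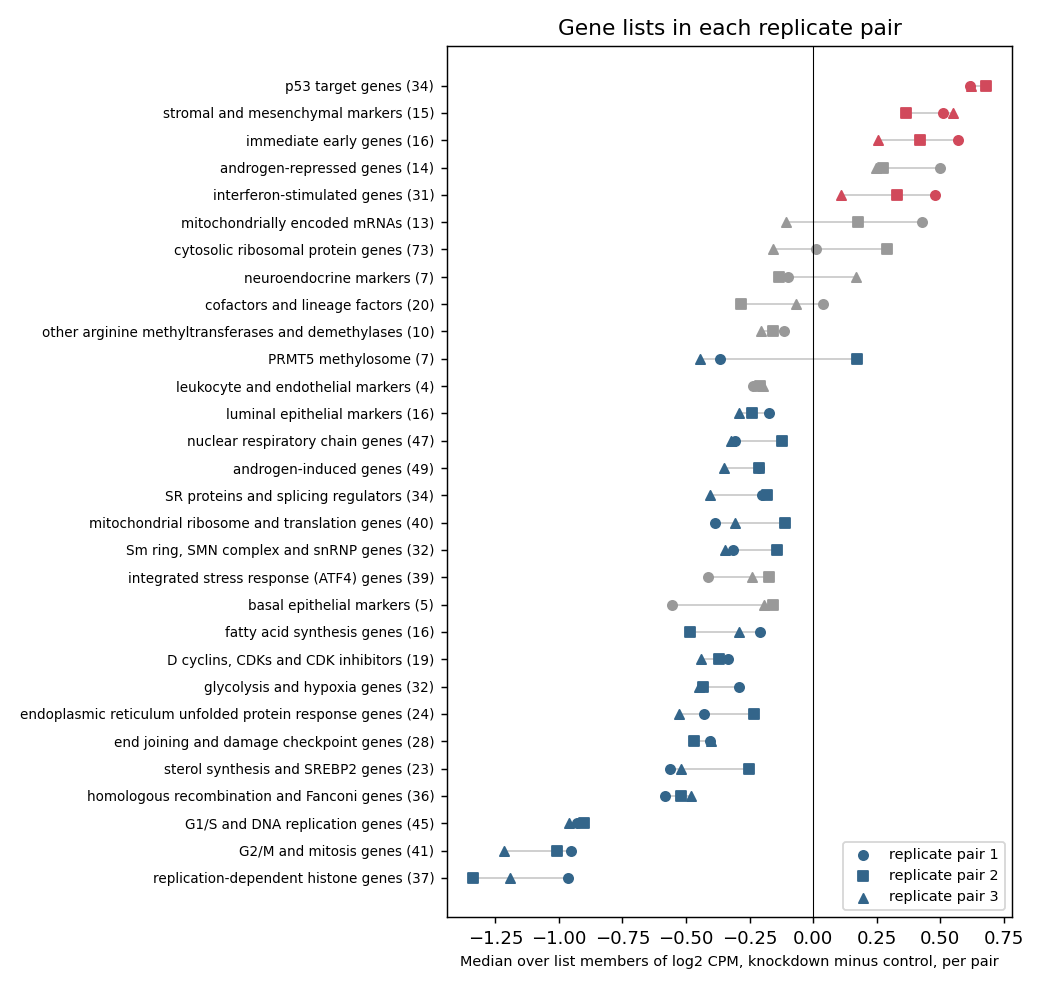
Median over the tested members of each list of the log2 CPM difference, knockdown minus control, in each replicate pair, with the number of members in parentheses. Red marks the lists that camera called higher and blue those it called lower without the block, grey marks those not called, and the histone, G2/M and G1/S lists lie below -0.90 in all 3 pairs while p53 targets lie between 0.62 and 0.68.

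Antisense transcripts made up 46 of the higher and 75 of the lower calls, and 221 and 235 of those with the pairs as a block. The strand setting of the counting is not stated, so reads of an antisense gene and its partner cannot be told apart.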

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

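The fits with the block that left out a pair, used DESeq2 or an estimated correlation, and the fits on coding genes without the word CTCTGT, were chosen after seeing the data. The other alternatives were set before.

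The fall of WDR77 was called under each alternative, with log2 fold changes from -1.80 to -1.55. RLE scaling, the bias-adjusted quasi-likelihood test and leaving out mitochondrial genes ended no list call and moved no count of calls over all tested genes by more than 1.5 times. The 1603 changed genes (574 higher, 1029 lower) became 3148 (1336, 1812) with no count filter, where more genes were tested, and 2608 (1015, 1593) in edgeR's exact test. DESeq2 called 899 higher. An adjusted p under 0.01 left 388 (106, 282), and a log2 fold change of at least 1 left 800 (349, 451). Over the fits that left out 1 library, which have fewer samples, the counts ranged from 497 to 1423 changed, 168 to 500 higher and 329 to 923 lower. Without knockdown replicate 2, 488 of the 1603 calls were shared.

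With the replicate pairs as a block the counts were 5506 (2358, 3148), and with the block and DESeq2 4413 (1799, 2614). Without pair 1, 2 or 3 the block fit called 3158 (1372, 1786), 7409 (3648, 3761) and 4572 (1948, 2624). In camera at the preset correlation, the block brought the androgen-repressed list (0.0151) and the ATF4 list (0.00113) past the threshold and changed no other list call. It brought 21 of the 33 named genes that were not called past the threshold and changed no other call among named genes. With an estimated correlation besides the block, the androgen-repressed and ATF4 lists had 0.334 and 0.438, and in fry with the block they had 0.0435 and 0.0646. Without pair 1, 2 or 3 and with DESeq2, the block gave 0.0374, 0.0164, 0.00986 and 0.00544 for the androgen-repressed list and 0.02, 0.00017, 0.000916 and 0.000786 for the ATF4 list. Without pair 3 it also called the mitochondrially encoded (0.0124) and ribosomal (0.0114) lists. For the counts, the smaller residual spread with the block is part of the difference. For the lists the cause was not tested.

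Lists depended most on whether the inter-gene correlation was preset or estimated. With an estimated correlation camera gave 0.403 for the PRMT5 methylosome, androgen-induced, recombination, end joining, G1/S, G2/M, SR protein, immediate early and stromal lists. It gave 0.395 for D cyclins, 0.503 for the Sm and mitochondrial translation lists, 0.326 for the histone and endoplasmic reticulum lists, 0.491 for the respiratory chain, 0.553 for interferon, 0.239 for the sterol and luminal lists, and 0.0932 for glycolysis. This test widens the null by the correlation of members within groups. It also has only the residual degrees of freedom, 4 without the block and 2 with it. Its power is therefore low, and a lost call does not show that a list was unchanged. Set against the mean over all libraries, list medians of single libraries overlapped between the groups in some called lists. These were the methylosome, androgen-induced, recombination, D cyclin, Sm, respiratory and interferon lists. Fry gave 0.107 for the androgen-induced, recombination, end joining, G1/S, G2/M, respiratory and mitochondrial translation lists. It gave 0.0904 for the methylosome, 0.125 for Sm, 0.0924 for SR proteins, 0.0666 for histones, 0.294 for interferon, 0.13 for immediate early and 0.132 for stromal genes. With the block fry called the G1/S (0.00108), G2/M (0.0197), recombination (0.0177), end joining (0.00982) and histone (0.0246) lists. It also called the stromal (0.0352), Sm, SR protein and basal (0.0474 each) lists. It did not call the methylosome (0.0791), androgen-induced (0.0554), respiratory (0.0979), mitochondrial translation (0.0751), interferon (0.135) or immediate early (0.0647) lists. The luminal list, called by fry without the block (0.0124), was not called with it (0.0514). With the block and an estimated correlation no called list kept its call, at 2 residual degrees of freedom. The values were 0.35 for the methylosome, Sm, SR protein and immediate early lists and 0.334 for androgen-induced, endoplasmic reticulum and luminal genes. They were 0.211 for recombination, end joining, G2/M, D cyclins, histones and fatty acid synthesis, and 0.0997 for G1/S. They were 0.141 for p53 targets, 0.5 for the respiratory and mitochondrial translation lists, 0.457 for interferon, 0.239 for sterol, 0.266 for glycolysis and 0.257 for stromal genes. Over all alternatives the adjusted p of the p53 list ranged from 3.86e-21 to 0.141, of G1/S from 1.32e-51 to 0.403 and of G2/M from 2.37e-56 to 0.403.

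The cause was not tested for these list calls. The ATF4 list was called with no count filter (0.00629). Interferon genes lost their call in limma-voom (0.0644) and immediate early genes in counts thinned to the smallest library (0.144). Leaving out 1 library moved 6 lists across the threshold. Over those fits the adjusted p ranged from 0.00114 to 0.336 for interferon, 0.0039 to 0.131 for stromal, 4.98e-05 to 0.895 for ATF4, 0.0322 to 0.294 for basal, 0.016 to 0.12 for immediate early and 0.0212 to 0.908 for ribosomal genes. Of the 84 named genes that were called, 40 were called in all 6 such fits. Among uncalled named genes the sign changed in 8 combinations of gene and alternative, and in no called gene.

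Restricted to the 6502 coding genes without CTCTGT in the 3' UTR, 343 genes were called (158, 185), and all were among the 1603. WDR77 was left out of these genes as the target of the hairpin, although its 3' UTR lacks the word. The fatty acid list turned from a median of -0.39 to 0.03 (camera adjusted p 0.898, range over its alternatives 1.6e-12 to 0.898). Calls were lost for the methylosome (0.0549), end joining (0.0591), D cyclins (0.221), SR proteins (0.0549), interferon (0.424) and luminal (0.0503) lists, and the basal list was called (0.0191). With the block in the same genes, calls were lost for the methylosome (0.109), D cyclins (0.223), interferon (0.223), fatty acid (0.737) and luminal (0.231) lists, and the androgen-repressed list was called (0.00534). These lists have fewer members there, which is part of the cause. The median of the methylosome list was -0.35 and that of end joining -0.37 without the word, against -0.21 and -0.45 before, so the losses in these 2 lists do not show that the word carried the change. The methylosome list there held 4 genes and not WDR77, so the removal of WDR77 may account for its lost call. Thinning to the smallest library moved no count of calls over all tested genes by more than 1.5 times, and 1431 of the 1603 calls were shared.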

Other observations

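The tests of a 6-base site, of the length and composition of the 3' UTR, and of a rising integrated stress response were chosen only after the result was seen, as were the genes named in the next paragraph.

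Several changes lay outside the lists. PTBP2, the neuronal relative of the splicing repressor PTBP1, rose from 34.4 ± 1.57 to 152 ± 19.5 CPM (log2 fold change 2.14, SE 0.13, adjusted p 0.000219, edgeR), while PTBP1 had a log2 fold change of -1.09. The heterochromatin protein gene CBX5 fell from 499 ± 79.7 to 124 ± 12.1 CPM (-2.01, adjusted p 0.000646), and the histone chaperone gene SET fell from 600 ± 109 to 144 ± 18.1 CPM (-2.06, adjusted p 0.000667). CBX5, SET and PTBP2 all have the word CTCTGT in the 3' UTR. PEG3, an imprinted gene, fell from 8894 ± 551 to 3676 ± 1352 CPM (-1.27, adjusted p 0.0232). The nuclear RNA MALAT1 took 1.20%, 1.96% and 1.65% of the counts in the knockdown libraries and 0.576%, 0.974% and 1.28% in the controls, with group ranges that overlap, and was not called (0.181) without the block and was with it (0.0119). Coding genes took 90.1%, 89.4% and 90.2% of the counts in knockdown and 92.1%, 92.2% and 91.6% in control libraries.

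Transcripts with the 6-base word CTCTGT in their 3' UTR fell more often than others. Over 13228 coding genes with an annotated 3' UTR, WDR77 left out, this word had the lowest regression t of all 4096 words (-13.97). The next word that does not overlap it had -5.16, and the highest t was 4.4. With an A before the word and an A after it (499 genes) 20.04% of genes were lower and 3.01% higher, with a median log2 fold change of -0.19. With the A before alone (1993 genes) 11.59% were lower, with the A after alone (1120 genes) 12.41%, with the word alone (3114 genes) 6.10%, and without it (6502 genes) 3.57% were lower and 2.92% higher. With the pairs as a block the ratio of these shares was smaller and their difference larger, with 184 of the 499 lower and 43 higher, against 1020 of the 6502 lower and 836 higher. The word was in 74.0% of the 892 lower genes searched and in 94.0% of the 50 lower genes with the smallest p, against 50.8% of all. WDR77 holds ACTCTGT once in its coding sequence, on chromosome 1 from 111444073 to 111444079 (GRCh38), in all 4 annotated transcripts. Of all 7-base words 15.1% occur in WDR77, so its presence there is weak evidence. D cyclin list members had a median of -0.87 with the word and -0.18 without it, fatty acid genes -0.56 and 0.03, and interferon genes, in the other direction, 0.84 and 0.06.

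Length or composition of the 3' UTR alone is argued against as the source of the link between the word and the falls. The t of -13.97 was reached after adjustment for length, base composition, CpG content and abundance. No t without adjustment was computed, and the shares of lower genes above are not adjusted. Whether length or composition adds to the falls was not tested. Repression through a 6-base site is consistent with the values, as the word found on odd chromosomes (t -9.48) was again the lowest of all on the others (t -10.29, 6040 genes). Repression by the seed of the hairpin against WDR77 may explain it, but cannot be told apart from a small RNA of the cell that changed with treatment, because there was 1 hairpin and its sequence is not used here. The lowest 7-base word, CTCTGTA (t -13.26), is not in WDR77, which the test set beforehand required, while ACTCTGT, at the next rank (t -13.22), is. Both words hold CTCTGT and their t values are close, so their order does not decide for or against the hairpin. The fall of the fatty acid list may belong to this pattern, with an adjusted p of 0.898 without the word (range 1.6e-12 to 0.898), whereas the G1/S (1.14e-12), G2/M (2.42e-15) and p53 (2.42e-15) lists were called among genes without it at the preset correlation, calls that over all genes were lost with an estimated correlation for G1/S and G2/M (0.403 each) and, with the block added, for p53 (0.141).

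Among called coding genes with at least 5 CPM in control cells, 5 fell further than WDR77: TMPRSS11E, SNX12, CLU, ANAPC13 and ACLY. For these the log2 fold change plus 2 of its standard errors lay below that of WDR77 minus 2 of its own. ANAPC13 (84.0 ± 10.5 to 13.6 ± 1.54 CPM) was named after its values were seen. A long stretch shared with WDR77 is argued against, since the longest run shared by any of them was 14 bases, where 19 would match a hairpin in full. A shared seed cannot be told apart from chance here. At most 4 of the 5 shared a 7-base word of WDR77, as many as in 91.99% of 10000 gene sets matched on 3' UTR length. The absence of a word in all 5 had been set beforehand as evidence against a seed, but 62.1% of matched sets equalled 5 genes that do share a word, so the test had no power, and CTCTGT itself is in 4 of them and not in CLU.

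The changes between libraries with and without doxycycline could come from the drug as well as from the knockdown. No net rise of the integrated stress response was seen in the libraries with the drug. The ATF4 list was lower in every pair, with its highest pair median at -0.17, but was not called without the block (camera adjusted p 0.112). A rise from the drug offset by a fall from the knockdown cannot be excluded, since drug and knockdown come together. A drug effect on mitochondria cannot be told apart from the knockdown, as the mitochondrially encoded mRNAs had a camera adjusted p of 0.274 (range over alternatives 0.0124 to 0.849) while nuclear respiratory and translation lists were lower at the preset correlation but not with an estimated one (0.491 and 0.503), and no library had the drug alone. A shift of the cells out of cycle is consistent with the joint fall of the G1/S and G2/M lists (2.44e-17 for G2/M, range 2.37e-56 to 0.403), and either the drug or the knockdown could give it. A biological effect of lower MEP50 stays open and untested.

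The 6 libraries can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real division gave 1603 genes, 1 of the 10 reached that number, and edgeR called 0 in each of the others, with 70 to 2540 at an unadjusted p under 0.05. Each of those others mixes knockdown and control libraries within its groups. The difference between the treatments then adds to the spread within groups, so few calls could arise and the contrast with 1603 is weak evidence. The 3 others that part every pair gave 70 to 186 at an unadjusted p under 0.05, and 0 calls with the block against 5506. DESeq2 and limma-voom were not run on them.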
